A study of Drosophila melanogaster with 6 samples.

How the data were processed

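Total RNA of whole Drosophila melanogaster larvae of instar 1 was isolated with TRIzol and RNeasy columns, labelled with biotin and hybridised to Affymetrix arrays by the standard protocol, per the labels' protocols. The labels put 3 arrays in the wild type group and 3 in the Pof mutant group, each from 200 larvae, and numbers 1 to 3 name the replicates within a group. No label gives a batch, a scan date, the parents' stocks or the nature of the mutation.

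The deposited values are log2 expression values per probe set, made with RMA per the submitters' processing notes; its version and settings are not given in the sources used here. RMA as commonly run corrects background, quantile-normalizes the arrays together and summarises the probes of a set. Quantile normalization gives all arrays nearly the same distribution, so a shift of most genes in one direction would be removed, and folds of dim probe sets are compressed toward 0. Array medians (6.44 to 6.55) and lower quartiles (5.10 to 5.23) were close. No detection calls were used, so whether a dim probe set lay above background is unknown, and the number of arrays limits the precision.

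The arrays held 18952 probe sets, and 183 control probe sets were left out of all tests, leaving 18769. Genes were named from a table of the platform's annotation, in which 13647 of these probe sets had 1 gene symbol, 402 had several and 4720 had none. Symbols and chromosomes were updated through the gene ID in a reference table of the Release 6 plus ISO1 MT assembly, which held the ID of 13544 of the single-gene probe sets and was used only for names, chromosome arms, order, distances and lengths of genes. A gene was represented by its single-gene probe set with the highest mean over the 6 arrays, which gave 11982 genes, 11893 of them with a chromosome; 1094 genes had over 1 probe set. Probe sets with the suffixes _s, _x and _a can match several transcripts, and close copies in a gene family can share signal.

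All probe sets were fitted together in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on both groups without covariates, and p-values were adjusted by Benjamini-Hochberg over all tested probe sets. An adjusted p under 0.05 is a call. Differences are mutant-labelled minus wild type, SE is the moderated standard error, and ± is the SD over the 3 arrays of a group. Replicate arrays were compared by Pearson correlation and the SD of their difference before use.

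Before the data were examined, the following were set: the groups, the limma design, the rule for named genes, 23 gene lists, the chromosome 4 symbol list, the 1 Mb window around Pof and the alternatives, except those called chosen after the data were seen. Lists and chromosome arms with at least 5 measured genes were compared with all other genes by limma's camera with a preset correlation of 0.01 and again with the correlation estimated per list, and fry tested whether members move one way on balance; these p-values were adjusted over the 23 lists, or over 6 arms. The chromosome 4 shift is the median difference of its genes minus that of the genes on X, 2L, 2R, 3L and 3R, with a 95% bootstrap interval over genes, 10000 random lists matched on mean expression, and a two-sided exact permutation test of the per-array medians. Shares of genes were compared by two-sided Fisher's exact tests, which treat genes as independent. The lists of detoxification, cell cycle, cuticle and other genes were written by hand from general knowledge; some members belong to more than 1 tissue.

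Named genes were Pof, the 12 largest rises and the 12 largest falls among called genes whose groups do not overlap, the 10 chromosome 4 genes with the smallest p, up to 4 members of each list with the smallest p, roX1 and roX2, and the 3 nearest measured genes on each side of Pof. Some of these, mainly members of lists without a call, are left out of the text for length. Genes outside this rule are said to have been chosen after their values were seen.

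Alternatives were filters to the upper 60% and 40% of probe sets by mean, a further quantile normalization, cyclic loess, centring on the large arms, eBayes with trend and robust, array weights, the replicate number as a block, each array left out in turn, the mean over the probe sets of a gene, leaving out _s, _x and _a probe sets, an adjusted p under 0.10, an added 1.5-fold threshold, a linear model without eBayes, a 500 kb window, and other summaries of chromosome 4. Leaving out wild type replicate 1 and Pof mutant replicate 2 together, and camera with an estimated correlation, were added after the data were seen.

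The procedure was tested on simulated data of the same 18769 probe sets and 6 arrays. Over 5 runs with 200 changed probe sets, 52.0% of the 100 changed by 1.5-fold and 86.2% of the 100 changed by 2-fold were called, with a mean of 6.6 false calls. A given chromosome 4 shift of -0.15 was found as -0.16 on average, and 0 lists were called. The noise was drawn independently for each probe set, without correlated genes or a deviating array. The simulation therefore cannot show how many false calls of genes or lists such correlation gives.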

Results

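RNA from whole Drosophila melanogaster larvae of instar 1 was measured on 6 Affymetrix expression arrays, 3 of wild type larvae and 3 of larvae labelled as mutant for Pof. Each array is described in the labels as a separate biological replicate made from 200 larvae, with sexes and tissues mixed. Pof encodes a protein known to bind along chromosome 4 of the fly. The design asks which transcripts differ between larvae with and without the mutation. Log2 expression values of 18769 probe sets were compared, and probe sets naming a single gene covered 11982 genes. Array medians lay between 6.44 and 6.55. Values came without detection calls, and the number of arrays limits their precision.

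The arrays of a group were not equally alike. Wild type replicates 2 and 3 correlated with r = 0.998 over all probe sets, and the SD of their difference was 0.13 (log2). They shared 0 identical values and differed by over 2-fold on 5 probe sets. Both were kept because the labels name them as biological replicates; their values do not show whether they came from separate RNA, and 201 and 218 genes were called when replicate 2 or 3 was left out, against 490 with both. Pairs of mutant-labelled arrays correlated with r between 0.993 and 0.996, with an SD of the difference between 0.20 and 0.26. Wild type replicate 1 correlated with the other wild type arrays at r = 0.980 and r = 0.979, with an SD of the difference of 0.43. On that array 158 genes lay over 4-fold above the mean of the other wild type arrays and 0 lay as far below. Members of 4 families linked to cuticle formation were frequent among the 158, with 15 of 24 Twdl, 19 of 66 Cpr, 8 of 24 Osi and 2 of 7 Lcp genes. On Pof mutant replicate 2 the control probe sets for actin, GAPDH and eIF-4a had a mean 3' minus 5' difference of 2.03, against 1.20 to 1.48 on the other arrays.

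Pof itself gave a higher signal on the mutant-labelled arrays than on the wild type arrays. The values were 6.74, 6.83 and 6.82 on the wild type arrays (mean 6.80 ± 0.05, SD, n = 3) and 8.35, 8.44 and 8.43 on the mutant-labelled arrays (8.41 ± 0.05, SD, n = 3). Its signal was therefore 3.06-fold higher under the mutant label (log2 difference 1.61, SE 0.07, limma adjusted p = 9.47e-05). Pof (CG3691, arm 2R) was read by 1 probe set with a single gene name, of the suffix _s. A signal above wild type would go against the label if the mutation lowers the measured transcript, but what the mutation does is not given. The groups are therefore called wild type and mutant-labelled below, and every direction rests on those labels. The position of the probe set relative to the mutation is not given in the sources used here, so it is not known whether it can check the labels. The noncoding RNA genes roX1 and roX2 had no paired probe set.

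Between the groups, 490 genes passed an adjusted p of 0.05, of which 318 were higher and 172 lower on the mutant-labelled arrays. Among them 64 were over 2-fold higher and 46 over 2-fold lower. The largest rise was that of the cytochrome P450 gene Cyp6a17, from 5.07 ± 0.24 to 11.0 ± 0.14 (SD, n = 3), which is 60.4-fold (log2 5.92, SE 0.13, adjusted p = 4.93e-06). Its wild type mean lay below the lower quartile of every array (5.10 to 5.23), so the size of that fold is uncertain. CG4650 rose 8.10-fold (adjusted p = 9.15e-05), CG9259 rose 6.91-fold (2.10e-05) and CG2065 rose 5.24-fold (8.13e-04). The wild type means of CG4650 and CG9259 (4.49 and 4.81) also lay below every lower quartile, so the sizes of their folds are uncertain too. A further cytochrome P450, Cyp6w1, rose by 1.78 (SE 0.14) and the UDP-glycosyltransferase Ugt35E2 by 1.77 (SE 0.22) on the log2 scale. AANATL2, related to arylalkylamine N-acetyltransferases, rose 3.35-fold, the annexin AnxB10 3.29-fold and Adk3 3.16-fold. CG12744 and CG32379 rose 3.30-fold and 3.26-fold. The gene shep, which encodes an RNA-binding protein, rose by 1.70 (SE 0.18, adjusted p = 4.27e-03) on its brightest probe set. That call was lost when probe sets with the suffixes _s, _x and _a were left out (log2 difference 0.35, adjusted p = 0.104), and the mean over all shep probe sets was 0.46.

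Among the falls, CG31342 went from 8.78 ± 0.52 to 4.36 ± 0.17 (SD, n = 3), 21.3-fold lower on the mutant-labelled arrays (log2 -4.41, SE 0.24, adjusted p = 2.89e-04). The cytochrome P450 genes Cyp12d1-d and Cyp9c1 were lower as well: Cyp12d1-d fell by 4.18 (SE 0.13, adjusted p = 2.21e-05) and Cyp9c1 fell by 2.84 (SE 0.10, adjusted p = 3.16e-05). The mutant-labelled means of CG31342 and Cyp12d1-d (4.36 and 4.35) lay below the lower quartile of every array (5.10 to 5.23). The sizes of their falls are therefore uncertain. A probe set that names both Cyp12d1-d and its close copy Cyp12d1-p fell by 2.75 (adjusted p = 5.15e-04), so the copies are not fully separated. The chromosome 4 gene Zip102B, named for zinc transporters, was 9.91-fold lower and CG40298 11.9-fold lower. Also lower were the formin gene dia (5.66-fold), CG5181 (5.21-fold), the alkaline phosphatase gene Alp7 (4.96-fold), and BomS6 and BomS4 (4.62-fold and 4.36-fold), which encode Bomanin immune peptides. Ppcs, a gene of coenzyme A synthesis, fell by 2.69 (SE 0.23, adjusted p = 1.84e-03). Without wild type replicate 2 or 3 another Ppcs probe set had the highest mean, and its differences were -0.11 and -0.17 (adjusted p = 0.926 and 0.779). CG1894 fell by 2.26 (adjusted p = 1.62e-03) on an _s probe set, while its remaining probe set gave 0.094 (adjusted p = 0.756).

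Probe sets of a gene did not always move together. Of the 30 called genes with another single-gene probe set, 18 had only differences of the same sign and 2 had another probe set that was also called. RFeSP, the Rieske subunit of respiratory complex III, was chosen after its values were seen. A dimmer RFeSP probe set went from 5.72 ± 0.11 to 10.8 ± 0.08 (SD, n = 3; log2 difference 5.13, SE 0.09, adjusted p = 1.03e-06). The brighter RFeSP probe set, which stands for the gene in all counts, differed by -0.11 (adjusted p = 0.667). Probe sets without a single gene made up 81 of the 601 called, and the largest fall among those without any name was -3.79 (adjusted p = 9.67e-06).

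For all 490 called genes the 3 values of one group lay beyond those of the other, as they also did for 2194 genes that were not called, and chance alone gives 10% for 3 against 3. At an unadjusted p under 0.05 there were 2009 genes. The number of calls moved by over 1.5 times when single arrays were left out, to 201 and 218 genes without wild type replicates 2 and 3, and to 255, 300 and 280 without mutant-labelled replicates 1, 2 and 3. It was 536 without wild type replicate 1, and 403 of the 490 genes were called there with the same sign. Without both wild type replicate 1 and mutant-labelled replicate 2 it was 712, with array weights 840, with an added 1.5-fold threshold 306, and without moderated variances 55.

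Genes of detoxification, a list of cytochromes P450, glutathione S-transferases and UDP-glycosyltransferases, differed often between the groups. Of 61 measured members, 21 rose, 7 fell and 33 did not pass. Besides Cyp6a17 and Cyp6w1, Cyp28d1 rose by 1.19 (adjusted p = 5.18e-04), while Cyp12d1-d and Cyp9c1 fell. Adjusted over the list alone, 26 rose and 7 fell. The share called was 45.9%, against 3.88% of all other genes (95% interval of the odds ratio 12.1 to 36.2, two-sided Fisher's exact test, adjusted p = 7.91e-22), a test chosen after the data were seen. The list's median difference was 0.22, and camera gave an adjusted p = 1.68e-04 toward higher values. With an estimated correlation the adjusted p = 0.556, and fry gave an adjusted p = 0.0367. Without wild type replicate 1, 20 members rose and 7 fell, and without mutant-labelled replicate 2, 15 rose and 7 fell.

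**Figure D1:**
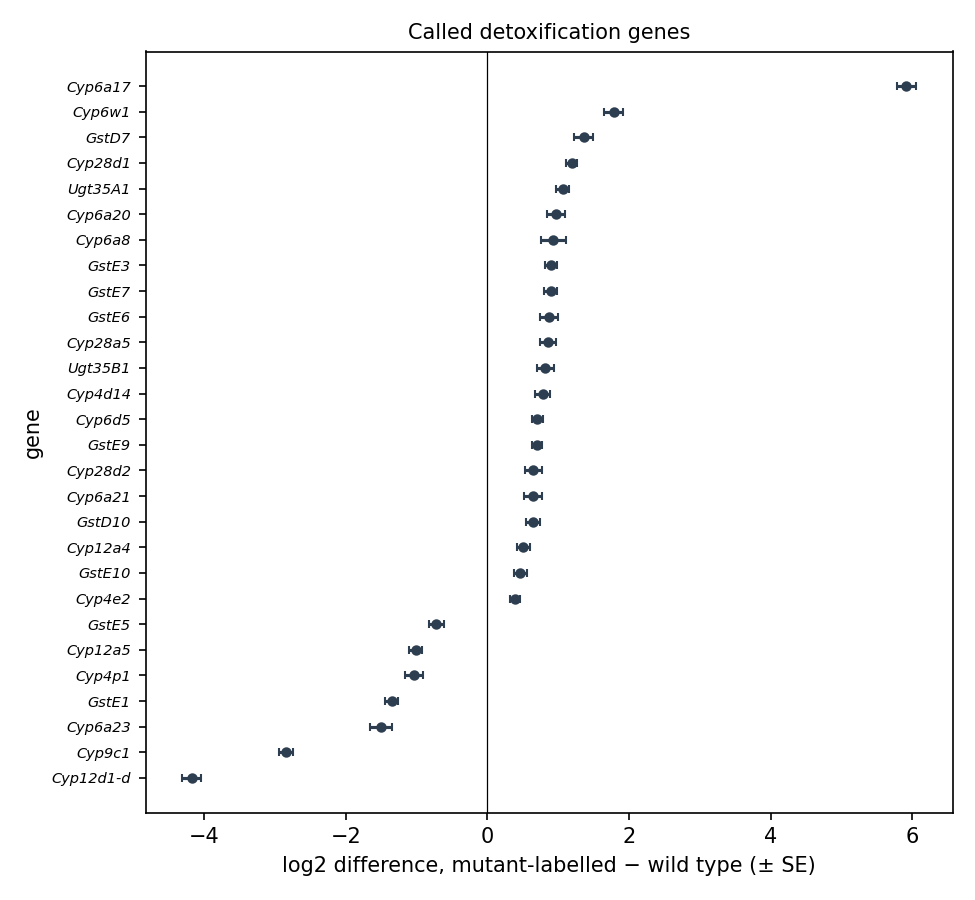
Log2 difference (mutant-labelled minus wild type, n = 3 arrays each) of the 28 called genes of the detoxification list, with bars of 1 SE from the limma fit. The 21 genes to the right of 0 rose and the 7 to the left fell, with Cyp6a17 at 5.92 and Cyp12d1-d at -4.18 at the ends.

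Cell cycle and replication genes lay higher on the mutant-labelled arrays as a list. Of 19 members 2 rose and 0 fell: the mitotic cyclin gene CycB3 by 0.56 (SE 0.09, adjusted p = 0.0250) and fzy, an activator of the anaphase-promoting complex, by 0.60 (adjusted p = 0.0431). CycB and the securin gene pim differed by 1.62 and 1.02 without passing (adjusted p = 0.0560 and 0.0571); CycB passed without mutant-labelled replicate 1 or 2 (0.0357 and 0.0247). Adjusted over the list alone 10 rose and 0 fell, and at an unadjusted p under 0.05 limma gave 10 higher and 0 lower. The median difference was 0.28, with a camera adjusted p = 2.18e-04, and the adjusted p = 0.556 with an estimated correlation. CycB3 lost its call without wild type replicates 2 or 3 or mutant-labelled replicates 1 or 2 (adjusted p between 0.0583 and 0.115). The call of fzy was lost without any array except mutant-labelled replicate 1 (0.0537 to 0.159), after quantile normalization or cyclic loess (0.0997 and 0.10), and as the mean of its probe sets (0.22, adjusted p = 0.168). Without both wild type replicate 1 and mutant-labelled replicate 2, 6 members rose and 0 fell; without the first alone 1 rose and without the second alone 2 rose.

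Midgut and digestion genes moved both ways. Of 41 members 5 rose and 2 fell. Among those that rose, the serine protease genes Jon44E and Jon99Ci differed by 1.31 and 0.98 and Npc2d, of a family of sterol-binding proteins, by 0.91. The remaining rises, betaTry (1.03) and Jon74E (0.59), are also serine protease genes, and Jon25Bi, another one, fell by 0.61. These last 3 were chosen after their values were seen. The lipase gene mag fell by 1.23. Adjusted over the list alone 13 rose and 3 fell, and the share called was 17.1% against 4.04% elsewhere (odds ratio 4.88, two-sided Fisher's exact test, adjusted p = 0.0141), again chosen after the data were seen. The list did not pass camera (adjusted p = 0.0586; 0.750 with an estimated correlation). With all 6 arrays it did pass after either filter on dim probe sets (0.0337 and 0.0304), a further quantile normalization (0.0312), centring on the large arms (0.0453) or cyclic loess (0.0259), and without _s, _x and _a probe sets (0.0406). It also passed without wild type replicate 1 (0.0176), when 10 rose and 4 fell, and without wild type replicate 3 (0.0321) or mutant-labelled replicate 3 (0.0495), and it gave 0.143 without mutant-labelled replicate 2, when 3 rose and 1 fell. With the preset correlation its adjusted p ranged from 0.0176 to 0.143 over the settings. The call of Jon99Ci was lost without wild type replicate 2 or mutant-labelled replicates 1 or 2 (adjusted p 0.0593 to 0.0856), and that of betaTry without wild type replicates 2 or 3 or mutant-labelled replicate 2 (0.0739 to 0.101). Those of Jon74E and Jon25Bi were each lost without wild type replicates 2 or 3 or mutant-labelled replicate 2, that of Jon74E also without mutant-labelled replicate 1 and after cyclic loess (0.0519 to 0.126), and that of Jon25Bi also without mutant-labelled replicate 3 (0.0645 to 0.153). The call of mag was lost without mutant-labelled replicates 1 or 3 (0.0673 and 0.0638).

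Cuticle genes lay lower on the mutant-labelled arrays as a list, and this rested on 1 wild type array. None of the 38 members passed limma, 0 did when adjusted over the list alone, and at an unadjusted p under 0.05 there were 0 higher and 4 lower. Examples are TwdlL at -1.87, Cpr67Fa2 at -0.84, Cpr100A at -0.66 and Cpr47Eb at -0.34. The median difference was -0.29 with a camera adjusted p = 5.27e-03, and with an estimated correlation the adjusted p = 0.852. Wild type replicate 1 had a list median of 9.08, against 6.83 to 7.30 on the other arrays. Without that array the list's median difference was 0.044 (adjusted p = 0.647), 1 member rose and 1 fell, and TwdlL was called at -0.86, while Cpr67Fa2 was called at -1.02 without wild type replicate 2. The list's call was also lost with array weights (adjusted p = 0.271). Genes of ecdysone response and moulting had 0 calls among 26 members by limma, with 1 higher and 3 lower at an unadjusted p under 0.05, and 0 higher and 2 lower when adjusted over the list alone. That list gave a camera adjusted p = 0.133, or 0.0299 without wild type replicate 2, and an adjusted p = 0.785 with all arrays and an estimated correlation, with ImpL2 at -0.41 and Eip78C at -0.59.

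**Figure D2:**
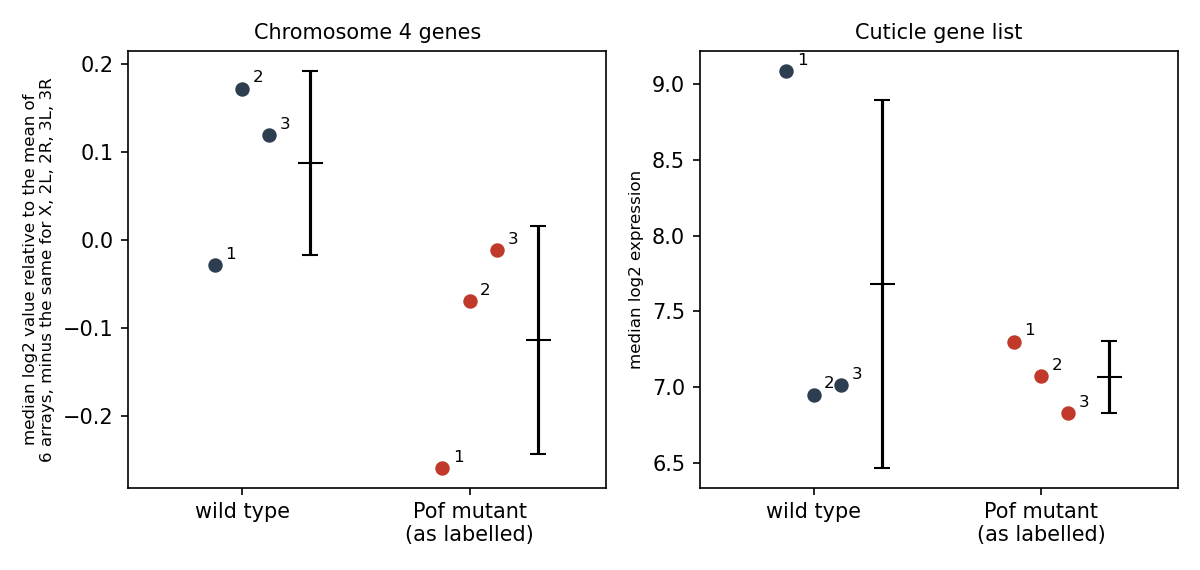
Left, median log2 expression of 65 chromosome 4 genes on each array, relative to the mean of the arrays and to the genes of the large arms; right, median log2 expression of the 38 cuticle list genes on each array, with points for arrays and lines and bars for group mean and SD (n = 3). On the left the groups overlap, since wild type replicate 1 at -0.029 lies below mutant-labelled replicate 3 at -0.011; on the right wild type replicate 1 lies at 9.08 and the other arrays between 6.83 and 7.30.

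Neuronal genes and genes of embryonic patterning also lay lower as lists, with few single calls. Of 21 neuronal genes 0 rose and 1 fell, the synaptic vesicle priming gene unc-13 (-0.63), which lies on chromosome 4. The neuronal RNA-binding gene fne gave -0.83 (adjusted p = 0.0912, or 0.0254 without mutant-labelled replicate 2) and the monoamine transporter gene Vmat -0.43. Adjusted over the list alone 0 rose and 2 fell, and at an unadjusted p under 0.05 limma gave 0 higher and 3 lower. The camera adjusted p = 0.0101, or 0.750 with an estimated correlation. The list's call was lost without mutant-labelled replicate 1 (adjusted p = 0.137). Of 18 patterning genes 0 rose and 1 fell, the pair-rule gene odd (-0.39, adjusted p = 0.0454), and the same 0 and 1 resulted when adjusted over the list alone, with 0 higher and 2 lower at an unadjusted p under 0.05. Kr gave -0.40 (-0.53 and called without wild type replicate 1) and twi -0.17. Its camera adjusted p = 0.0379 became 0.750 with an estimated correlation. That call was lost without wild type replicates 2 or 3 (0.0858 and 0.0622), without mutant-labelled replicates 2 or 3 (0.0598 and 0.111), and with the dimmest probe sets left out (0.158 and 0.268). The call of odd was lost without any single array (adjusted p between 0.0520 and 0.181) and with trended variances (0.0663).

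Of the remaining lists none passed camera with the settings used throughout, and each held at most 1 call. Of 25 pericentric genes, which lie in or beside heterochromatin, Scp1 rose by 0.68 and Dbp80 gave 0.55 (adjusted p = 0.0552, or 0.0376 without mutant-labelled replicate 1); adjusted over the list alone 3 rose and 0 fell. The pericentric list gave an adjusted p = 0.0553 (0.785 with an estimated correlation) and passed without wild type replicate 2 (0.0299) or mutant-labelled replicate 1 (6.37e-03). With all 6 arrays it passed with the 60% filter on dim probe sets, quantile normalization, centring, cyclic loess, array weights, the mean of probe sets or without _s, _x and _a probe sets (0.0259 to 0.0453), and the highest value with the preset correlation was 0.304. Of 21 heterochromatin regulators the histone deacetylase gene HDAC1 rose by 0.80, also the only call when adjusted over the list alone with 1 rise and 0 falls (camera adjusted p = 0.180, or 0.0437 without wild type replicate 2; adjusted p = 0.852 with all arrays and an estimated correlation). Of 15 maternal germline genes stau fell by 0.36 (adjusted p = 0.0450), a call lost without any single array (0.0798 to 0.207) and with trended variances (0.0727), and grk gave 0.51. Of these 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.389). Of 12 fat body genes the lipocalin gene Karl rose by 0.54 (adjusted p = 0.0294), lost without any array but wild type replicate 1 (0.0752 to 0.112) and under both other treatments of probe sets (0.0851 and 0.309). In that list 2 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.569).

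Among 23 immune genes the antibacterial peptide gene Listericin rose by 1.26, and Mtk, which encodes metchnikowin, gave 2.55 without passing (adjusted p = 0.0833), but 3.33 and a call without mutant-labelled replicate 3 (adjusted p = 2.78e-03). Of the immune genes 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.189, or 0.0337 without mutant-labelled replicate 3; adjusted p = 0.852 with all arrays and an estimated correlation). The list did not hold the Bomanin genes BomS6 and BomS4, which were called lower (-2.21 and -2.13). Of 17 genes of nutrient and insulin response Pepck2, related to the gluconeogenic enzyme PEPCK, fell by 1.17 and Akh gave 0.41; adjusted over the list alone 1 rose and 1 fell (camera adjusted p = 0.796). Of 74 genes of oxidative phosphorylation UQCR-11, a subunit of complex III, fell by 0.34 (adjusted p = 0.0462) and none passed when adjusted over the list alone (camera adjusted p = 0.713). The call of UQCR-11 was lost without any single array (0.0841 to 0.195), after quantile normalization (0.0693) and with trended variances (0.0664).

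By limma 0 genes were called in the lists of heat shock, dosage compensation, Y-linked, testis, ovary, muscle, glia, hemocyte and ribosomal protein genes, with 8, 8, 7, 27, 16, 18, 11, 16 and 40 measured members. Many named genes were not measured, since the heat shock list named 20 genes, the Y-linked list 12 and the ribosomal protein list 92. At an unadjusted p under 0.05 limma gave 2 higher and 0 lower heat shock genes, 0 and 1 of dosage compensation, 1 and 1 of muscle, 1 and 0 of glia, 2 and 1 of hemocytes, 2 and 1 of ribosomal proteins, and 0 and 0 in the lists of Y-linked, testis and ovary genes. Adjusted over the list alone 1 heat shock gene rose and 0 passed in the others. Their camera adjusted p were 0.789 (heat shock), 0.857 (dosage compensation, Y-linked, testis, ovary and hemocytes alike), 0.789 (muscle), 0.713 (glia) and 0.992 (ribosomal proteins). Members with the smallest p in these lists included Hsp27 at 0.71, the dosage compensation gene msl-3 at -0.34, the muscle gene sls at 0.43 and the hemocyte gene NimC1 at 0.39. Camera compares a list with all other genes, and it pointed down for dosage compensation, Y-linked, ovary, ribosomal protein and oxidative phosphorylation genes although their medians and means lay above 0. For testis genes the median was -0.0048 and the mean 0.014. Of all 23 lists tested 5 passed with the preset correlation and 0 with an estimated one. By fry, of these 5 only detoxification passed, and the adjusted p was 0.0516 for cell cycle, 0.325 for patterning, 0.339 for neuronal and 0.672 for cuticle genes. Camera with an estimated correlation gave its smallest unadjusted p for detoxification (0.0470) and cell cycle genes (0.0484). Their estimated correlations were 0.050 and 0.097.

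Chromosome 4 genes were lower on the mutant-labelled arrays. The median difference of the 65 measured genes, relative to the genes of the large arms X, 2L, 2R, 3L and 3R, was -0.16 (95% bootstrap interval over genes -0.20 to -0.11), which is 10.5% lower. Of these genes 53 lay below the large-arm median (81.5%, 95% Wilson interval 70.4% to 89.1%). In all 6 genes fell and 0 rose: Zip102B (-3.31), the yellow family gene yellow-h (-1.18, adjusted p = 8.73e-03), the TGF-beta family ligand gene mav (-1.0, adjusted p = 5.55e-03), CG31997 (-0.85), CG31999 (-0.65) and unc-13 (-0.63). The apolipoprotein gene apolpp gave 0.40 (adjusted p = 0.0714), Taf3, named for a TFIID subunit, -0.36 (adjusted p = 0.109), Asator -0.47 and CG32006 -0.32, and none of these passed. Without wild type replicate 1 apolpp and Taf3 were called (0.48 and -0.44). At an unadjusted p under 0.05, 11 genes were lower and 1 higher, and adjusted over the arm alone 7 fell and 1 rose.

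Camera separated chromosome 4 from the other genes (adjusted p = 1.46e-06 over the 6 arms), but with the estimated correlation, 0.21, the adjusted p = 0.907, and fry gave an adjusted p = 0.236. Taken per array, the median relative to the large arms was -0.029, 0.17 and 0.12 on the wild type arrays (mean 0.088 ± 0.10, SD, n = 3) and -0.26, -0.070 and -0.011 on the mutant-labelled arrays (-0.11 ± 0.13, SD, n = 3). The difference of -0.20 gave p = 0.2 in a two-sided exact permutation test, whose smallest possible p is 0.1. The median lay below all of 10000 random lists matched on mean expression, whose central 95% ran from -0.046 to 0.045. Of the chromosome 4 genes 6 of 65 fell, against 166 of 11917 others (1.39%, two-sided Fisher's exact test, p = 3.29e-04), chosen after the data were seen. A list of chromosome 4 symbols written beforehand held 61 of these genes, with 0 rises and 6 falls, 1 and 6 adjusted over the list alone, and a camera p of 4.24e-07 (0.156 with an estimated correlation). Without mutant-labelled replicate 1 the shift was -0.084 and 3 genes fell; 3 also fell without wild type replicate 2 or 3, and 13 without both wild type replicate 1 and mutant-labelled replicate 2. CG31997, CG31999 and unc-13 each lost their call without 4 of the arrays in turn, wild type replicates 2 and 3 and mutant-labelled replicate 1 among them for each (adjusted p up to 0.0896, 0.10 and 0.118). Mutant-labelled replicate 3 was the other array for CG31997 and unc-13 (0.0642 and 0.0880), and replicate 2 for CG31999 (0.0569).

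**Figure D3:**
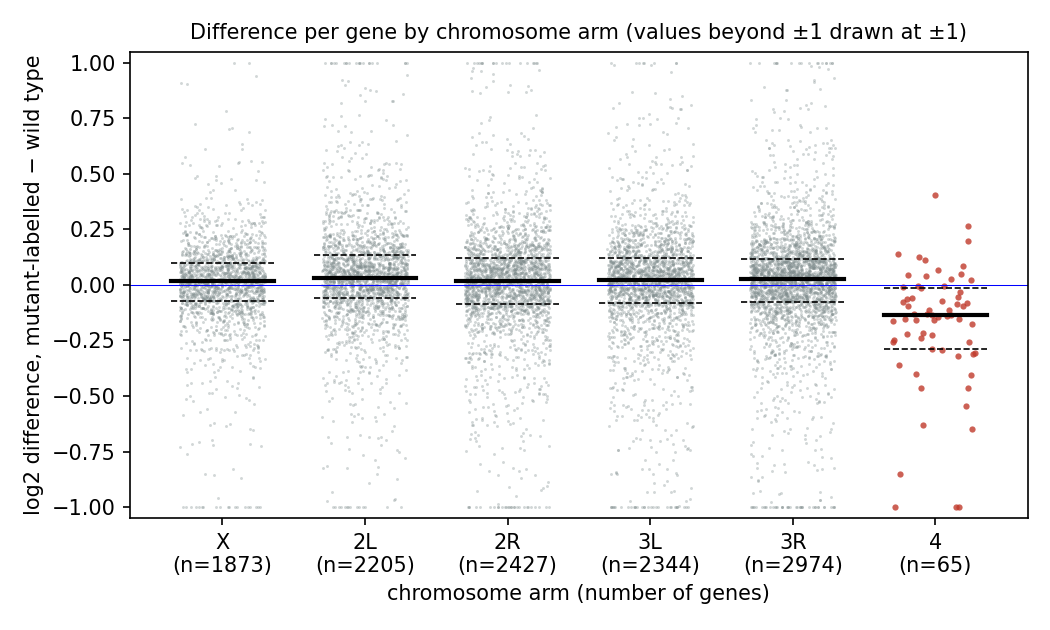
Log2 difference (mutant-labelled minus wild type, n = 3 arrays each) of every measured gene by chromosome arm, with values beyond 1 or -1 drawn at those limits; solid lines mark each arm's median and dashed lines its quartiles. Medians of the large arms lie between 0.016 and 0.033, and that of chromosome 4 lies at -0.14.

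On none of the large arms did the genes shift as a group. Their median differences were 0.016 on X, 0.033 on 2L, 0.018 on 2R, 0.022 on 3L and 0.026 on 3R, and each camera adjusted p = 0.853. Camera pointed down for X, 2R and 3L although their medians lay above 0; the mean lay below 0 on X and 3L and above 0 on 2R. The share of genes called did differ, by tests chosen after the data were seen. On X 34 of 1873 genes were called (1.82%), against 4.51% of all other genes (odds ratio 0.391, 95% interval 0.267 to 0.557, two-sided Fisher's exact test, adjusted p = 3.19e-08). Within 10 bins of mean expression the odds ratio was 0.382. Without wild type replicate 1 the X share was 1.71% (odds ratio 0.331), and without mutant-labelled replicate 2 it was 0.854% (odds ratio 0.298). On 2L and 2R 5.17% and 5.07% of genes were called (adjusted p = 0.0164 for each by Fisher's exact test), and on 3L and 3R 3.46% and 4.44% (0.110 and 0.263). On chromosome 4 it was 9.23% (0.0738).

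The genes around Pof on 2R were compared with the rest of that arm. The 3 nearest measured genes on each side, by their order in the Release 6 plus ISO1 MT assembly, were not called. ND-19, CG34214 and CG33228 gave 0.02, 0.22 and 0.37, and Mid1, Usp15-31 and spz6 gave -0.33, 0.07 and -0.73. Of these, the adjusted p of CG33228 was 0.0952, and it was called after cyclic loess (0.35, adjusted p = 0.0495). ND-19 and Usp15-31 turned negative and spz6 positive without wild type replicate 1 (-0.030, -0.089 and 0.056). Within 1 Mb of Pof 10 of 249 genes were called (4.02%), against 112 of 2177 elsewhere on 2R (5.14%; odds ratio 0.772, two-sided Fisher's exact test, p = 0.541). Without wild type replicate 1 the log2 odds ratio turned from -0.37 to 0.025.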

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

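The cuticle list and 3' to 5' control tests on wild type replicate 1 were chosen only after the result was seen. So were those of chromosome 4 without that array, of the genes around Pof and of exchanged labels. The others were set before their own results were seen. Of these, the patterning test on wild type replicate 1 and the test of mutant-labelled replicate 2 name features of single arrays already seen in the data. Leaving out each array in turn was planned, and only its use to weigh wild type replicate 1 as an explanation came later.

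Control probe sets outside the main comparison stood out on single arrays, judged by a signal over 2-fold above the highest wild type array. On mutant-labelled replicate 2 the 18S ribosomal RNA probe sets read 10.8 at the 3' end, 9.10 at the 5' end and 12.7 in the middle (log2). The wild type maxima were 7.73, 6.55 and 9.56. On mutant-labelled replicate 3 a control probe set for the Bacillus subtilis dap transcript read 7.91 against a wild type maximum of 6.83. That transcript is added to samples as a spike. With 3 arrays per group, no array was tested as an outlier within its group.

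Cuticle genes were high on wild type replicate 1, while the ecdysone response and moulting list differed there by a median of only 0.15 from the other wild type arrays, with members on both sides of 0. The cuticle list had a median 0.84 above the mean of the other wild type arrays, and its 95% bootstrap interval over genes, 0.36 to 1.76, includes the 1 taken as the mark of larvae at another point of the moult, so the list leaves that explanation open. Embryos still patterning their segments would raise the patterning list, whose median was -0.060 (-0.23 to 0.055), and this argues against them. The patterning list does not bear on embryos past that stage, which were not tested. RNA degradation on that array is argued against too, since its mean 3' minus 5' difference of 1.37 lay within the 1.20 to 2.03 of the other arrays. A difference in age may remain, but it is not decided by these values, and no label gives the hours after hatching.

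Chromosome 4 genes were lower on the mutant-labelled arrays. Wild type replicate 1 had the lowest median of the wild type arrays (-0.029), so it made the shift smaller. Leaving it out was bound to enlarge the shift (-0.23, -0.30 to -0.18) and could not test it. Mutant-labelled replicate 2, the array with 3' bias and ribosomal RNA, had a median of -0.070, above the mutant-labelled mean of -0.11. Leaving it out was therefore bound to lower that mean and could not test these defects as the cause. The shift was -0.17 without that array (-0.23 to -0.13), so it was not confined to that array. Mutant-labelled replicate 1 had the lowest median of all arrays (-0.26), and without it the shift was -0.084. The expression level of these genes is argued against by the shift of -0.16, outside the -0.046 to 0.045 of lists matched on mean expression. A few genes with large falls are argued against by the 81.5% of genes below the large-arm median (70.4% to 89.1%). The intervals and matched lists here treat genes as independent, so they do not measure the spread between arrays. What stays open is a fluctuation shared by all genes of the chromosome on 3 arrays per group, because their estimated correlation was 0.21 and the per-array medians overlapped. An effect of the Pof mutation, which the labels name without saying what it does to the protein, stays open as an untested hypothesis.

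The Pof signal was higher on the mutant-labelled arrays. A rise of the whole region is argued against by the 6 nearest measured genes, whose median difference was 0.044 and whose values ran from -0.73 to 0.37, below the 0.8 set for that explanation. An exchange of labels between the whole groups cannot be told apart from a mutation that raises the signal of the measured part of the transcript, since both give the same difference of 1.61 and no second measured transcript marks the genotype. A probe set that only reads outside the mutation, or reads the Mmp1 gene that overlaps Pof in the reference, would leave a signal but not one above wild type unless the transcript it reads rose; neither was tested, because probe positions are not given in the sources used here and Mmp1 had no probe set of its own.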

How the results depend on the processing

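Camera with an estimated correlation and leaving out both wild type replicate 1 and mutant-labelled replicate 2 were chosen only after the data were seen. Pof was higher and called in every setting that measured it (1.56 to 1.64); leaving out _s probe sets removed it, and with it the comparison of its neighbourhood. The chromosome 4 shift stayed below 0 in every setting run (-0.084 to -0.24). Camera with the preset correlation called it in every setting, and 1 arm was called in each. With an estimated correlation camera gave chromosome 4 p = 0.156 (adjusted p = 0.907 over the arms), and no arm was called. Of 47 named genes that were called, 30 were called with the same sign in every setting that measured them, apart from the block. The 490 calls became 306 with an added 1.5-fold threshold, which only removes genes, 55 without eBayes, 840 with array weights (514 higher, 326 lower), 712 without both doubted arrays (379 higher, 333 lower) and 201 to 536 with 1 array left out (132 to 311 higher, 69 to 225 lower). The cause of these changes was not tested. Chromosome 4 falls numbered 3 to 8 with 1 array left out and 13 without both. With an estimated correlation 0 lists were called. Reversed values, whose cause was not tested, were those of ND-19 (-0.014 with array weights, -0.0022 without both arrays, -0.030 to 0.051 with 1 left out), Usp15-31 (-0.067, -0.27, and -0.11 to 0.21), spz6 (0.22 without both, -1.18 to 0.056 with 1 left out) and the log2 odds ratio of the Pof neighbourhood (-1.19 to 0.025 with 1 left out). The median of the cuticle list also turned, from -0.29 to 0.044 without wild type replicate 1 and to 0.081 without both arrays. The cuticle list lost its call there, and its high values on that array enter the difference directly. Some lists without a call in the main settings changed sign too. Examples without wild type replicate 1 are ecdysone and moulting genes (-0.055 to 0.014) and dosage compensation genes (0.070 to -0.033, and -0.13 without both arrays). CG1894 (0.094 without _s, _x and _a probe sets) and RFeSP (2.51 as the mean of its probe sets, 5.13 without those suffixes) reversed because another probe set then enters or stands for the gene.

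With the replicate number as a block, 476 genes were called (304 higher, 172 lower), and 44 of the 47 called named genes kept their call. Lists called went from 5 to 7, as the midgut and pericentric lists passed (adjusted p = 0.0193 by camera for each). Whether the numbers pair the arrays is not decided. Deviations from the group means correlated at 0.18, 0.13 and 0.025 for replicates 1, 2 and 3. The first was the highest between the groups, but wild type replicate 3 correlated best with mutant-labelled replicate 2 (0.15). Without detection calls, signal over background could not be judged, and dim probe sets are the least certain.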

Other observations

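Tests chosen only after the data were seen were those of gene families, of wild type replicate 1 and of the share of called genes on X; those of neighbouring calls, of chromosome 4 relations and of other splits were set before their results were seen.

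Among 158 families defined by the letters that open a gene's symbol, 5 held more called genes than the rest by two-sided Fisher's exact tests adjusted over the families, and the first 3 of them overlap the detoxification list. In the Cyp family of cytochromes P450, 14 of 83 genes rose and 7 fell (odds ratio 8.25, adjusted p = 1.68e-09). Of 35 Ugt genes 9 rose and 3 fell, and of 13 GstE genes 6 rose and 2 fell (adjusted p = 4.18e-07 by Fisher's exact test for each). Of 13 Jon serine protease genes 3 rose and 1 fell (adjusted p = 0.0465, Fisher's exact test). Of 5 AANATL genes, related to arylalkylamine N-acetyltransferases, AANATL2 and AANATL4 rose by 1.74 and 0.73 and AANATL3 fell by 0.72 (adjusted p = 0.0252 for the family, Fisher's exact test). All directions rest on the labels of the arrays.

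Wild type replicate 1 carried signals of some genes far above those on the other arrays. Osi6 read 12.5 there against 4.70 as the mean of the other wild type arrays and 4.61 to 6.11 on the mutant-labelled arrays. TwdlM read 13.9 against 7.35, Lcp65Af 12.5 against 5.20, CG13445 12.3 against 4.95 and Osi15 10.8 against 4.62. Genes over 4-fold higher on this array made up 62.5% of Twdl genes, 33.3% of Osi genes and 28.8% of Cpr genes, against 1.20%, 1.25% and 1.17% of other genes.

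A hypothesis on the genetic background of the larvae was tested by the position of called genes. Stocks that differ in linked segments of autosomes could give called genes next to each other. Among 11882 pairs of neighbouring measured genes 52 had both called, above the central 95% of 10000 shuffles within arms (14 to 31). Without pairs whose symbols share their start there were 34 (13 to 30 in shuffles), although copies known only by CG numbers remain. These values are consistent with a difference in background, and also with co-regulated neighbours, which no test here separates; the labels do not describe the stocks. The low share of called genes on X (1.82% against 4.51% elsewhere) was seen before this hypothesis was framed and is no test of it.

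Across the 65 chromosome 4 genes, which are not independent replicates, the difference between the groups had a Spearman correlation of 0.016 with mean expression (permutation p = 0.898, adjusted 0.898) and 0.11 with gene length (permutation p = 0.367, adjusted 0.733). Pearson's r was 0.033 and 0.25 (permutation p = 0.798 and 0.0434). Neither relation passed as ranks after adjustment for the 2 relations, which does not show that there is none.

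The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 490 genes and the highest other called 0, so 1 of the 10 gave as many genes. The real division called 5 lists and the highest other 8, with wild type replicate 1 beside mutant-labelled replicates 2 and 3. Thus 3 of the 10 gave at least as many lists.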
